A study of Arabidopsis thaliana with 32 samples.

How the data were processed

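S2P RNAPII ChIP-seq was made from seedlings of Col-0 and tfiis-1 at 4 times of heat shock, with 3 ChIP libraries and 1 input library per genotype and time (32 samples: 24 ChIP and 8 input). Per the labels' protocols, plants were crosslinked with formaldehyde, nuclei were isolated, chromatin was sheared in a Bioruptor, and immunoprecipitation used antibody ab5095 against S2P RNAPII. Libraries were made with the NEBNext Ultra II kit and 9 PCR cycles, per the labels' protocols. The series' design text calls the libraries biological triplicates. Bowtie2, FastQC, MACS3, deepTools and the genome build TAIR10 are named in the submitters' processing notes, without versions or roles. The threshold of the calls, the scaling between genotypes, the treatment of duplicates, multi-mapped reads and inputs, and whether replicates were pooled are not given in the sources used here. A scaling or pooling step acts on every call, so it can change how many sites are called in each direction.

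The authors deposited 8 lists, 2 directions at each of 4 times, with 32357 lines in all. Each line gives a summit of 1 bp, and the gene, with its strand, that holds it. The score in 2 of the lists (Col-0-higher at 10 min and 30 min) is the authors' own value per summit as deposited; its scale is not stated, the lowest is 2.01, and it was used only to rank or filter summits within a list. Those lists also give peak names and gene coordinates. The 936 gene intervals compared (922 different genes, those in both lists counted in each) all equal those of the RefSeq table of the TAIR10.1 assembly. Every summit lay inside its named gene, so positions were computed with that table. Coordinates are given in TAIR10, only for genes whose coordinates the lists hold. All 9114 gene identifiers matched it; symbols were taken from it. Repeated lines were counted once, leaving 29485 summits. A summit inside 2 overlapping genes (at most 163 per list) was counted in each gene. One gene was not annotated as protein-coding and was left out of overlaps and gene groups. Summits between genes are not analysed here.

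Since no list holds a value per library, no test of the genotypes over replicates, no test leaving out a replicate and no other split of the samples could be computed, and the precision that depth gives is unknown. Shares are given with exact (Clopper-Pearson) 95% intervals and compared by two-sided Fisher's exact tests. Median positions and gene lengths were compared by two-sided permutation tests with 100000 resamples, in lists of at least 20 members. Gene overlaps and gene groups were tested by two-sided Fisher's exact tests against 27444 nuclear protein-coding genes. The p-values were adjusted by Benjamini-Hochberg within each family, and the threshold was 0.05. Expected numbers and permutation p-values at matched gene length were taken within 10 strata of gene length, with 100000 draws. The tests were tested on simulated data: unmatched, the overlap test called 100% of 50 pairs of unrelated lists drawn in proportion to gene length, and 4% when matched on length. The position test called 5% of 40 pairs from one distribution at the sizes of the 30 min lists and 100% when one list was moved by 0.1 of the gene.

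The comparisons, alternatives, gene groups and the rule for named genes were set before the data were examined. The rule takes TFIIS, the 8 highest-scoring genes per list, up to 5 members of each gene group per list, up to 8 genes called in one direction at 3 or more times, and up to 6 genes called in opposite directions at different times; 212 genes were taken. In the 6 lists without scores, genes were ranked by their number of summits, then by shorter length, then by identifier, an order chosen after the lists were seen. Annotation classes of summits were not compared, because the lists hold summits in genes, all but 1 protein-coding, and intron numbers were not compared, because no exon annotation was used here. Alternatives were a stricter score, genes in place of summits, merging of summits within 300 bp, genes of at least 1000 bp, another background, summits within 500 bp in place of a shared gene, and, added after the lists were seen, the highest-scoring 50% of summits of the Col-0-higher lists that have scores, 1 position per gene, summits in 1 gene only, matching on gene length and genes of 1 direction only. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.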

Results

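RNA polymerase II (RNAPII) carrying the Ser2-phosphorylated form of the C-terminal domain (S2P), the mark of elongating polymerase, was mapped by ChIP-seq in Arabidopsis thaliana seedlings. The plants were grown in vitro and taken 14 days after stratification. Wild-type Col-0 was compared with tfiis-1, a mutant of TFIIS, the elongation factor that helps backtracked RNAPII resume transcription. Seedlings were taken without heat shock (0 min) and after 10 min, 30 min and 3 h of heat shock. Each of the 8 groups of genotype and time had 3 ChIP libraries from biological triplicates, 24 in all, and 1 input library, 8 in all. The data analysed here are 8 deposited lists of summits, the single base pairs at which one genotype was called above the other. A list called tfiis-1-higher holds sites of higher signal in tfiis-1, and one called Col-0-higher holds sites of higher signal in Col-0. The lists hold no value per library, so the depth is unknown, no spread between replicates could be computed, and a difference between the genotypes at a single site has no replicate check here. Tests below describe the lists: summits and genes are not replicates.

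The first question was how many sites differed between tfiis-1 and Col-0 before and during heat shock. At 0 min, 1527 summits in 1345 genes were tfiis-1-higher, and 41 summits in 31 genes were Col-0-higher. The few Col-0-higher genes at 0 min included ASN1 (AT3G47340), an asparagine synthetase, with 3 summits, BT2 (AT3G48360) with 3, and TCH4 (AT5G57560), a xyloglucan endotransglucosylase/hydrolase, with 2. The tfiis-1-higher list grew to 3743 summits in 2989 genes at 10 min, 8072 in 4550 genes at 30 min and 12084 in 6499 genes at 3 h. The Col-0-higher list held 72 summits in 69 genes at 10 min, 896 in 867 genes at 30 min and 3050 in 2957 genes at 3 h. LBA1 (AT5G47010), which encodes the RNA helicase of nonsense-mediated decay UPF1, went from 1 tfiis-1-higher summit at 0 min and 1 at 10 min to 7 at 30 min and 10 at 3 h. At 3 h 53.9% of the tfiis-1-higher genes held 2 or more summits, against 6.73% of the Col-0-higher genes, while at 0 min it was 12.4% against 25.8% (8 of 31 genes). The TFIIS gene itself (AT2G38560) was in none of the 8 lists, which checks nothing about the genotypes, since a mutation need not change the polymerase signal over the gene.

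**Figure D1:**
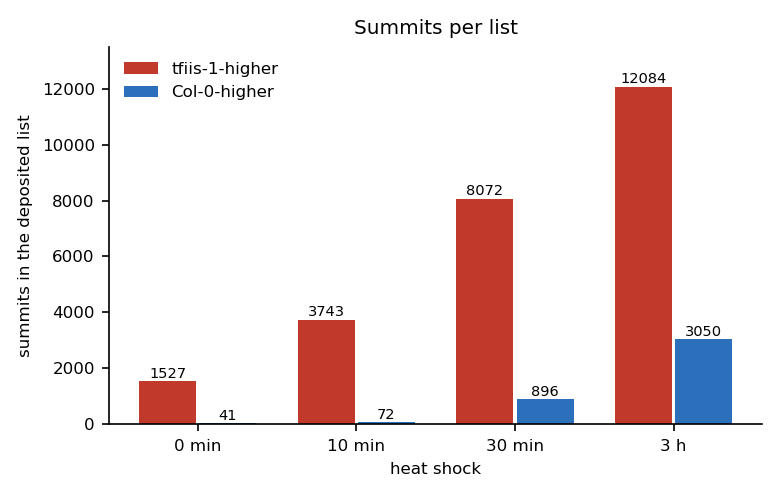
Number of summits (y axis) in the tfiis-1-higher lists (red bars) and the Col-0-higher lists (blue bars) at each heat shock time (x axis). Both directions held more summits at 30 min and 3 h, up to 12084 and 3050.

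The tfiis-1-higher share of all summits was 97.39% at 0 min (exact 95% interval 96.47 to 98.12), 98.11% at 10 min (97.63 to 98.52), 90.01% at 30 min (89.37 to 90.62) and 79.85% at 3 h (79.20 to 80.48). The share was lower at 30 min and at 3 h than at 0 min (two-sided Fisher's exact test, adjusted p = 1.31e-26 and 2.64e-90 over 3 tests), since the Col-0-higher list grew by a larger factor than the tfiis-1-higher list, which also grew. At 10 min it was not shown to differ from 0 min (adjusted exact p = 0.0946), and counting genes in place of summits reversed the sign of that small difference. The intervals cover counting error only, not the spread between libraries. Peak names in the Col-0-higher lists number up to 478 at 10 min and 1672 at 30 min, where the lists hold 72 and 896 summits. The other lists give no peak names, so whether all lists were filtered alike is unknown. The shares and their tests hold for the lists as deposited.

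The second question was where along the gene the sites lay, from 0 at the annotated start to 1 at the annotated end in the direction of transcription. At 0 min the tfiis-1-higher summits had a median position of 0.40, with quartiles of 0.27 and 0.55. Few of them lay in the first 10% of the gene. At 10 min they lay near the 3' end, with a median of 0.78 and 32.6% of them (31.1 to 34.1) in the last 10% of the gene. By 30 min the median was 0.51, and by 3 h it was 0.40, with 11.7% of summits (11.2 to 12.3) in the first 10% of the gene against 2.08% (1.43 to 2.92) at 0 min. Most Col-0-higher summits of the later times lay at gene ends: the median was 0.95 at 30 min and 0.95 at 3 h, and 63.5% and 65.5% of them lay in the last 10% of the gene, against 26.8% (14.2 to 42.9) at 0 min and 10.8% at 10 min. At 0 min and 10 min the short Col-0-higher lists had medians of 0.64 (41 summits) and 0.48 (74 pairs of summit and gene).

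Single genes showed these positions. In TOR (AT1G50030; TAIR10 chromosome 1, 18522248 to 18539995), the gene of the growth-regulating kinase target of rapamycin, 9 Col-0-higher summits at 30 min ran from position 0.40 to the gene end, while the 3 tfiis-1-higher summits lay between 0.04 and 0.15. The summit of TOR 78 bp from the gene end had the highest score in the Col-0-higher list at 30 min, 37.6 on the authors' scale. In BIG (AT3G02260; chromosome 3, 430877 to 448680) the 6 Col-0-higher summits at 3 h lay at 0.67 or beyond, and its tfiis-1-higher summit lay at 0.05. NRPB1 (AT4G35800; chromosome 4, 16960558 to 16968128), the largest subunit of RNAPII, had 1 tfiis-1-higher summit at 10 min at position 0.99, and a Col-0-higher summit at 0.99 both at 30 min and at 3 h. RAD50 (AT2G31970), a DNA repair gene, and HSFA3 (AT5G03720), a heat shock transcription factor, did otherwise: their highest-scoring Col-0-higher summits at 30 min (32.0 and 24.2) lay at the 5' end, at positions 0.0075 and 0.01.

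The difference in median position between the directions was -0.24 at 0 min, 0.30 at 10 min, -0.44 at 30 min and -0.55 at 3 h (tfiis-1-higher minus Col-0-higher). Compared with 0 min, the tfiis-1-higher median was further downstream by 0.39 at 10 min and by 0.11 at 30 min. Each of these 6 differences had an adjusted p of 1.17e-05 in a two-sided permutation test, from the smallest raw p that 100000 resamples can give (1e-05) over 7 tests. The seventh, 3 h against 0 min, did not pass (difference 0.0042, adjusted permutation p = 0.66).

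**Figure D2:**
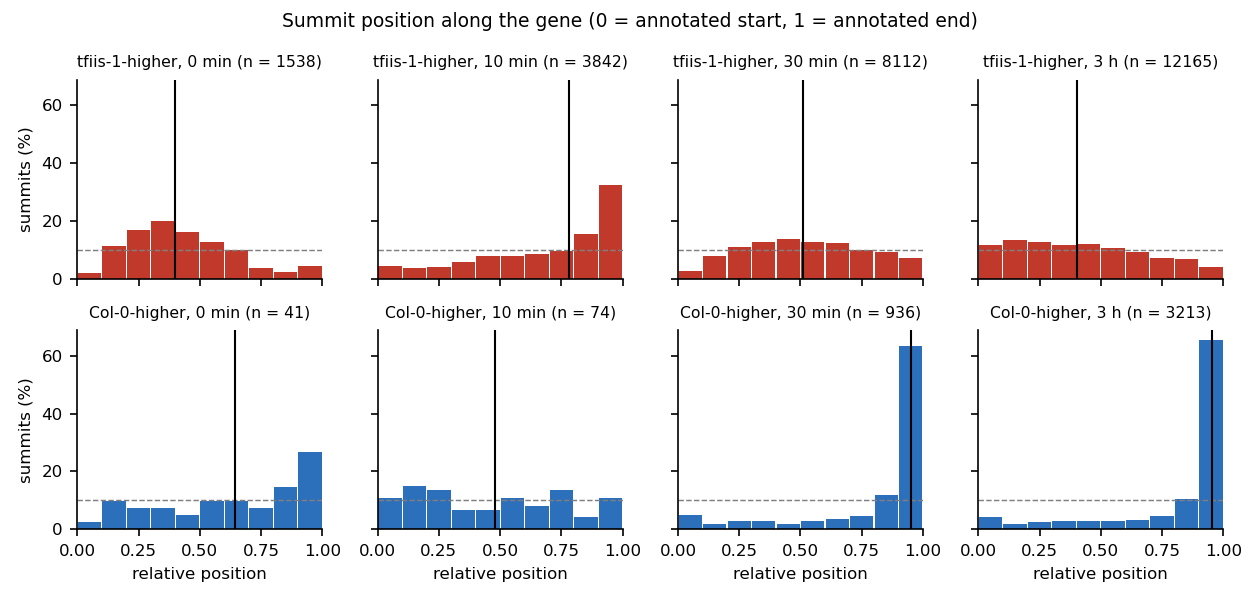
Share of summits (y axis, %) in each of 10 equal parts of the gene (x axis, 0 at the annotated start and 1 at the annotated end) for the 8 lists. The black line marks the median and the dashed line the 10% that an even spread would give. Col-0-higher summits at 30 min and 3 h pile up in the last part (63.5% and 65.5%), and so do tfiis-1-higher summits at 10 min (32.6%).

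The third question was whether the same genes were called at several times and in both directions. Of the genes in tfiis-1-higher lists, 538 were called at all 4 times, 1433 at 3, 2722 at 2 and 3487 at 1. GC6 (AT3G27530; chromosome 3, 10193477 to 10200046), a golgin, and KAK (AT4G38600; chromosome 4, 18040623 to 18049700), a HECT ubiquitin ligase of trichome development, were among the 538. In GC6 the number of tfiis-1-higher summits was 2, 3, 5 and 6 from 0 min to 3 h. Col-0-higher summits appeared 31 bp and 55 bp from its end at 30 min and 3 h, where the 10 min tfiis-1-higher summit had lain 36 bp from the end. Of the genes in Col-0-higher lists, 2760 were called at 1 time, 561 at 2, 14 at 3 and 0 at 4. The 14 included Hop3 (AT4G12400), an HSP70-HSP90 organizing co-chaperone, and the HSP70 gene AT3G09440.

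The tfiis-1-higher lists of 30 min and 3 h shared 3739 genes, where 1077 were expected. In 3381 of these genes summits of the lists lay within 500 bp of each other. The Col-0-higher lists of 30 min and 3 h shared 554 genes (93.4 expected), 517 of them with summits within 500 bp. The opposite lists of 3 h shared 1578 genes (700.1 expected), but in 187 of them (11.9%) summits lay within 500 bp. At 30 min the opposite lists shared 404 genes (143.7 expected), 47 of them with summits within 500 bp. The tfiis-1-higher list of 10 min shared 1242 genes with the Col-0-higher list of 3 h (322.1 expected), 951 of them (76.6%) with summits within 500 bp. Closeness was compared with reassigned positions for this last pair only, where the reassignments gave 673 to 749 genes. In the tfiis-1-higher lists 46.5% of genes at 30 min and 53.9% at 3 h held 2 or more summits. Part of the closeness can therefore arise without shared sites. The same holds for the Col-0-higher lists of 30 min and 3 h, where the median distance to the gene end was 136 and 117 bp. Few close summits in the opposite lists of 3 h can likewise follow from their median positions of 0.40 (tfiis-1-higher) and 0.95 (Col-0-higher).

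Of 28 pairs of lists, 20 shared more genes than expected and 1 shared fewer (two-sided Fisher's exact test, adjusted p under 0.05, background of 27444 nuclear protein-coding genes). The pair that shared fewer was the tfiis-1-higher list of 30 min with the Col-0-higher list of 10 min, with 4 genes where 11.4 were expected. The opposite lists of 10 min shared 14 genes (7.51 expected), 0 of them with summits within 500 bp, and this call was lost at matched gene length (adjusted permutation p = 0.0531). The genes of the lists were longer than the background median of 2078 bp, and lists of long genes overlap by length alone: with the expected value taken within 10 strata of gene length, 19 pairs stayed above expectation. With a background of the 9113 genes of any list, 9 pairs did, and the overlap of the opposite lists of 3 h fell to 0.748 of the expected number. Other pairs were then below expectation too. Among them were the tfiis-1-higher lists of 10 min and 3 h (0.860 of the expected number, adjusted exact p = 1.73e-47). The tfiis-1-higher list of 3 h with the Col-0-higher list of 30 min was another (0.818, adjusted exact p = 2.90e-17). This background is built from the same 8 lists, so each of its genes is in at least 1 of them. That pushes pairs below expectation, and these p-values do not show that lists avoid each other. Against all nuclear protein-coding genes the first of these 2 pairs was at 2.59 of the expected number, and at matched gene length at 2.04. Lists of one time come from the same libraries, and lists of different times do not.

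The fourth question was which known gene groups were called, using 10 lists written before the data were examined, and ribosomal proteins and histones taken from the annotation. None of the 89 heat-response genes (small heat shock proteins, large chaperones, heat shock transcription factors, co-chaperones) was in a list at 0 min. Few were expected in the tfiis-1-higher list (0.833, 1.47, 1.03 and 1.03 in this order of groups), and none of these absences passed. At 10 min, 12 of 30 large chaperone genes (HSP70, HSP90, HSP100 and HSP60 families) were tfiis-1-higher (3.27 expected, adjusted exact p = 2.27e-04), and 7 were Col-0-higher (0.0754 expected, adjusted exact p = 4.33e-11). Among co-chaperones and other heat-response genes, 12 of 21 were tfiis-1-higher at 10 min (2.29 expected, adjusted exact p = 5.98e-06) and 2 were Col-0-higher (0.0528 expected, adjusted exact p = 0.00435). In HSP90.1 (AT5G52640; chromosome 5, 21352557 to 21355147), the heat-induced cytosolic HSP90, the tfiis-1-higher summit at 10 min lay at position 0.11 and the Col-0-higher one at 0.67. The same order held in HSP70T-2 (AT2G32120; 0.21 and 0.94), the mitochondrial HSP70 gene MTHSC70-2 (AT5G09590; 0.19 and 0.80), Hop3 (AT4G12400; 0.16 and 0.99) and the heat shock factor gene HSFA2 (AT2G26150; 0.25 and 0.58). The Hop3 summit in Col-0 also lay inside the overlapping gene PME1 (AT4G12390). At 30 min 2 large chaperone genes were tfiis-1-higher (4.97 expected, adjusted exact p = 0.441), which was fewer than expected at matched gene length (7.80 expected, adjusted permutation p = 0.0437), and 5 were Col-0-higher (0.948 expected, adjusted exact p = 0.00761). At 3 h, 18 large chaperone genes were tfiis-1-higher (7.10 expected, adjusted exact p = 1.55e-04) and 14 were Col-0-higher (3.23 expected, adjusted exact p = 1.03e-05). HSC70-1 (AT5G02500), a constitutive cytosolic HSP70, had a tfiis-1-higher summit at 0.09 and Col-0-higher summits at 0.65 and 0.98 at that time. Small heat shock protein genes were Col-0-higher at 3 h in 8 of 17 cases (1.83 expected, adjusted exact p = 7.44e-04), among them HSP17.6A (AT5G12030) and HSP18.2 (AT5G59720). At 10 min 5 of them were tfiis-1-higher (1.85 expected), which did not pass (adjusted exact p = 0.0846), but did pass adjusted over the list alone (exact p = 0.0463) and at matched gene length (permutation p = 0.00651). Of 21 heat shock transcription factor genes, 9 were tfiis-1-higher at 3 h (4.97 expected, adjusted exact p = 0.164), which did not pass. How reads shared by near-identical gene copies, such as those of the HSP70 and HSP90 families, were treated is not given in the sources used here. Calls on single copies are therefore uncertain, and copies may not be independent members of a group. The same limit holds for any such copies in the groups below.

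Nuclear photosynthesis genes were tfiis-1-higher at 10 min in 32 of 57 cases (6.21 expected, adjusted exact p = 7.99e-15). They were Col-0-higher afterwards, 10 at 30 min (1.80 expected, adjusted exact p = 9.23e-05) and 25 at 3 h (6.14 expected, adjusted exact p = 5.87e-09). PSAL (AT4G12800; chromosome 4, 7521257 to 7522761), a photosystem I subunit, had a tfiis-1-higher summit at position 0.70 at 10 min and Col-0-higher summits at 0.97 at 30 min and 3 h. DRT112 (AT1G20340), a plastocyanin, and PSBO1 (AT5G66570), of the oxygen-evolving complex, were also tfiis-1-higher at 10 min and Col-0-higher at 30 min and 3 h, and PSBO1 was tfiis-1-higher at 30 min as well, further upstream (0.29 against 0.95). At 3 h, 3 of the 57 were tfiis-1-higher (13.5 expected, adjusted exact p = 0.00169), fewer than expected, but these genes are short (median 1464 bp), and at matched gene length this did not pass (8.67 expected, adjusted permutation p = 0.0946). Among the genes of any list the tfiis-1-higher count was below expectation at 3 h (26.4 expected, adjusted exact p = 8.92e-14) and also at 30 min, with 5 genes (18.5 expected, adjusted exact p = 1.72e-04). Against all nuclear protein-coding genes the 30 min count did not pass (9.45 expected, adjusted exact p = 0.316). At matched gene length 5.21 were expected at 30 min, close to the 5 found.

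Genes of the unfolded protein response of the endoplasmic reticulum were tfiis-1-higher at 10 min in 9 of 18 cases (1.96 expected, adjusted exact p = 2.33e-04), at 30 min in 8 (2.98 expected, adjusted exact p = 0.0159) and at 3 h in 14 (4.26 expected, adjusted exact p = 2.08e-05). At matched gene length the 30 min call was lost (adjusted permutation p = 0.304). They were Col-0-higher in 7 cases at 30 min (0.569 expected, adjusted exact p = 1.03e-05) and in 9 at 3 h (1.94 expected, adjusted exact p = 2.27e-04). BZIP60 (AT1G42990; chromosome 1, 16135723 to 16137463), a transcription factor of this response, had tfiis-1-higher summits at positions 0.51, 0.96, 0.19 and 0.05 from 0 min to 3 h, and Col-0-higher ones at 0.97 and 0.98 at 30 min and 3 h. SHD (AT4G24190), the HSP90 of the endoplasmic reticulum, and CRT1b (AT1G09210), a calreticulin, were tfiis-1-higher near the end of the gene at 10 min (0.97 and 0.90) and near its start at 3 h (0.05 and 0.08), and CRT1b had another tfiis-1-higher summit near its start at 10 min (0.07).

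Genes of SR splicing factors were tfiis-1-higher without heat shock in 8 of 20 cases (0.980 expected, adjusted exact p = 2.32e-05), then in 11 at 10 min (2.18 expected, adjusted exact p = 1.98e-05), 11 at 30 min (3.32 expected, adjusted exact p = 4.38e-04) and 13 at 3 h (4.74 expected, adjusted exact p = 4.38e-04). The ratio to the expected number was 8.16 at 0 min and 2.75 at 3 h. A longer list lowers the largest ratio that can be reached, so this fall does not show a change in these genes. They were Col-0-higher in 10 cases at 3 h (2.15 expected, adjusted exact p = 1.11e-04). RS41 (AT5G52040) was tfiis-1-higher at all 4 times and Col-0-higher at 0.97 and 0.98 at 30 min and 3 h. Of 20 genes of the RNAPII elongation machinery, 14 were tfiis-1-higher at 3 h (4.74 expected, adjusted exact p = 1.11e-04), among them SPT16 (AT4G10710), VIP5 (AT1G61040) and ELF7 (AT1G79730), and 7 were at 30 min (3.32 expected, adjusted exact p = 0.0964), which did not pass. Ribosomal protein genes were tfiis-1-higher in 8 of 67 cases at 0 min (3.28 expected, adjusted exact p = 0.0476; adjusted over the list alone, exact p = 0.0983), 19 at 10 min (7.30 expected, adjusted exact p = 3.33e-04) and 31 at 30 min (11.1 expected, adjusted exact p = 3.27e-07), and Col-0-higher in 19 at 3 h (7.22 expected, adjusted exact p = 3.04e-04). At 3 h 21 of them were tfiis-1-higher (15.9 expected, adjusted exact p = 0.316), which passed at matched gene length (11.1 expected, adjusted permutation p = 0.0136) and was below expectation among the genes of any list (31.4 expected, adjusted exact p = 0.0112). Among 12 housekeeping genes, 7 were tfiis-1-higher at 10 min (1.31 expected, adjusted exact p = 4.17e-04), 6 were at 30 min (1.99 expected, adjusted exact p = 0.0231) and 6 were Col-0-higher at 3 h (1.29 expected, adjusted exact p = 0.00298). The 30 min call was lost at matched gene length (adjusted permutation p = 0.126). Histone genes passed in no list (at most 3 of 20), and none of the 14 markers of root cell types and the guard cell lineage was in any list.

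Of 96 tests of 12 groups in 8 lists, 32 were above and 1 was below expectation (two-sided Fisher's exact test, Benjamini-Hochberg adjusted over the 96), and the counts were also 32 and 1 adjusted over the list alone. At matched gene length 30 of the 32 passed. The lists give no signal per gene, so groups could not be matched on signal, and its part in these calls was not tested. In the tfiis-1-higher list at 10 min the ratio to the expected number was 5.36 for housekeeping genes. It was 5.15 for photosynthesis genes, 5.25 for co-chaperones and 5.05 for SR factors. At matched gene length these ratios were 4.03, 6.82, 4.26 and 3.64. With the genes of any list as background, which holds called genes only, 13 of the 32 passed. These 13 included photosynthesis genes at 10 min, 30 min and 3 h, large chaperones in Col-0-higher lists at 10 min and 3 h, and SR factors at 0 min and 10 min. The calls above expectation in the tfiis-1-higher list of 3 h were all lost with this background: large chaperones (adjusted exact p = 0.722), co-chaperones (1), unfolded protein response (0.439), elongation machinery (0.0678) and SR factors (0.961). At 10 min the tfiis-1-higher calls of large chaperones (adjusted exact p = 0.164), the unfolded protein response (0.207) and ribosomal proteins (0.398) were lost as well, and at 30 min those of the unfolded protein response (1), SR factors (0.398) and housekeeping genes (0.722). In the Col-0-higher lists the calls of large chaperones (0.191) and co-chaperones (0.220) at 30 min and of co-chaperones (0.476), the unfolded protein response (0.207), SR factors (0.0678), housekeeping genes (0.212) and ribosomal proteins (0.398) at 3 h were lost (adjusted exact p in brackets), as was that of ribosomal proteins in the tfiis-1-higher list at 0 min (0.878). With this background 6 tests were below expectation, all in tfiis-1-higher lists: small heat shock proteins at 30 min (0 of 17, adjusted exact p = 0.0104) and 3 h (3, 0.0231), large chaperones at 30 min (0.00191), photosynthesis genes at 30 min and 3 h, and ribosomal proteins at 3 h. Of these 6, only large chaperones at 30 min also passed as below expectation at matched gene length. Small heat shock protein genes are short (median 1035 bp). At matched gene length 0.579 of them were expected at 30 min and 1.32 at 3 h. The 3 found at 3 h were thus not fewer than that, and the difference did not pass (adjusted permutation p = 0.613). With the highest-scoring 50% of the Col-0-higher summits of 30 min alone, 0 photosynthesis, large chaperone or co-chaperone genes were left at that time, where all summits held 10, 5 and 4. In the Col-0-higher lists, the calls of the unfolded protein response at 30 min (adjusted exact p = 0.576) and of co-chaperones at 10 min (adjusted exact p = 0.0876) were also lost with the highest-scoring 50%. The call of large chaperones at 10 min was kept (adjusted exact p = 0.00281), but its ratio to the expected number fell from 92.8 to 52.3. These genes thus made up a smaller share of the highest-scoring part of that list.

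**Figure D3:**
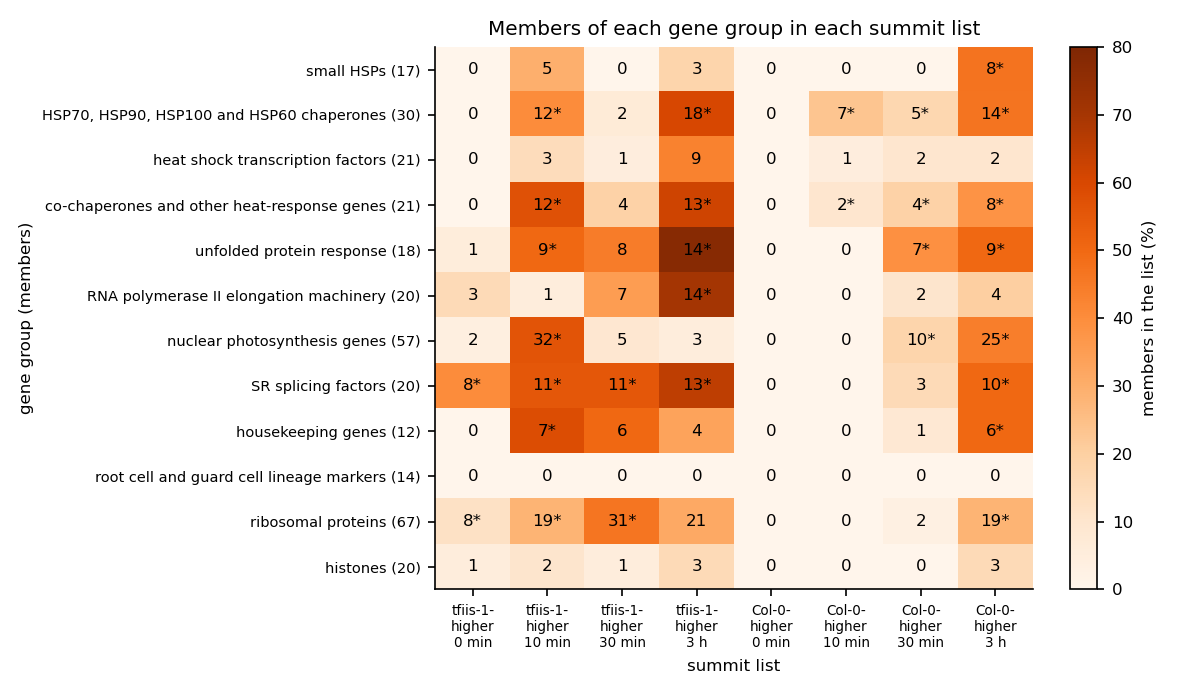
Number of members of each gene group (rows, group size in brackets) that held a summit in each list (columns), with the share of the group as colour (%). A star marks counts that passed both against all nuclear protein-coding genes and at matched gene length (adjusted p under 0.05). Photosynthesis genes have 32 of 57 members in the tfiis-1-higher list at 10 min and 25 in the Col-0-higher list at 3 h.

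The last question was whether the directions differed in gene length. Median gene length was 2613 bp in tfiis-1-higher and 2169 bp in Col-0-higher genes at 10 min (adjusted permutation p = 0.0234), 2978.5 and 2781 bp at 30 min (adjusted permutation p = 0.00558), and 2801 and 2575 bp at 3 h (adjusted permutation p = 4.00e-05; two-sided). At 0 min the medians were 2891 and 2664 bp over 1345 and 31 genes, and were not shown to differ (adjusted permutation p = 0.474). Long genes such as TOR, BIG and LBA1 were in both lists at 3 h. With the highest-scoring 50% of the Col-0-higher summits alone, the sign turned at 30 min (-174.5 bp, adjusted permutation p = 0.062), and at 10 min the difference did not pass (508 bp, adjusted permutation p = 0.062). Without the genes called in both directions at a time, the difference was larger, with 761 bp at 10 min, 696.5 bp at 30 min and 665.5 bp at 3 h (adjusted permutation p = 5.20e-04, 2.00e-05 and 2.00e-05). This left out 53.4% of the Col-0-higher and 24.3% of the tfiis-1-higher genes at 3 h, and 20.3% and 0.468% at 10 min. The larger difference can follow from this unequal removal, so it is no independent check.

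**Figure D4:**
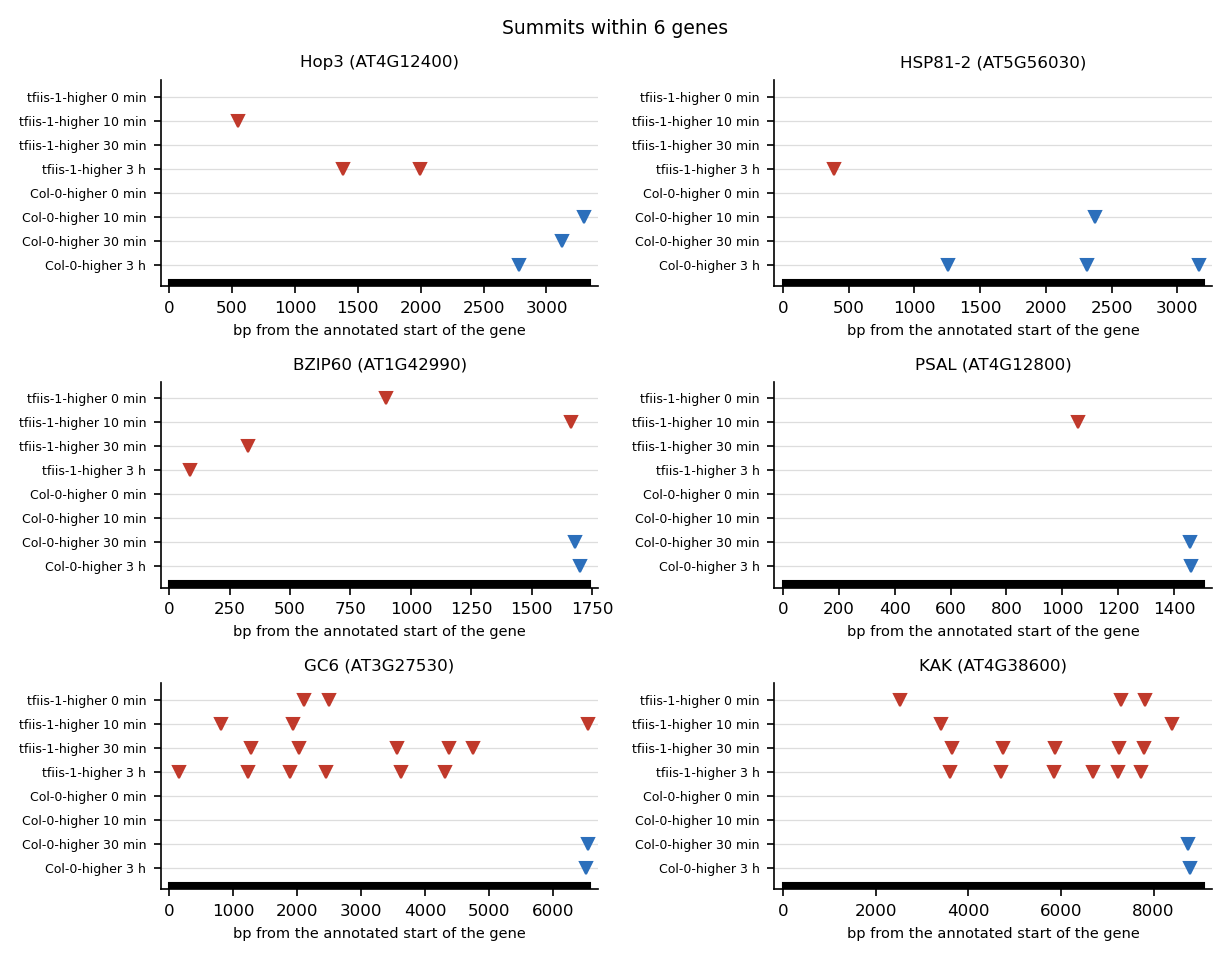
Summits (triangles) of the 8 lists (y axis) along 6 genes (x axis, bp from the annotated start, gene as a black bar), with tfiis-1-higher summits in red and Col-0-higher ones in blue. In Hop3 the 10 min summits lie at opposite ends (543 and 3298 bp from the start), and in GC6 the site near the end is tfiis-1-higher at 10 min and Col-0-higher at 30 min and 3 h.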

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

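Among the tests of explanations in this part, those of one scaling factor (at 3 h and over time) and of deeper libraries were chosen after the result was seen.

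The share of summits in the tfiis-1-higher list stood out because it differed between times: the change from 0 min was -7.38 percentage points at 30 min and -17.5 percentage points at 3 h, while the tfiis-1-higher list itself grew from 1527 to 8072 and 12084 summits and the Col-0-higher list from 41 to 896 and 3050. The position of tfiis-1-higher summits also differed between times, with a median 0.39 of the gene further downstream at 10 min than at 0 min, and 0.11 further at 30 min. Peak names in the Col-0-higher lists point to data not used in the comparisons. They number up to 478 at 10 min and up to 1672 at 30 min, while the lists hold 72 and 896 summits, which is 15.1% and 53.6% of the highest number.

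The pattern most open to follow-up is the opposed positions at 30 min and 3 h, with tfiis-1-higher summits upstream and Col-0-higher summits at the gene end. A single scaling factor between the genotypes, from depth or ChIP yield, would move sites one way, while both directions were called at 3 h (12084 and 3050 summits). This argues against it as the whole cause only. At 3 h, 53.4% of the 2957 Col-0-higher genes (1578) also held a tfiis-1-higher summit, but this share does not decide the question. Unrelated lists of these sizes would share 700.1 genes, or 2108 among the genes of any list. Scaling together with other differences between the libraries stays open. Signal of a neighbouring gene is also argued against: in the 650 genes with no other gene overlapping or within 1000 bp downstream, 61.6% of 745 Col-0-higher summits at 3 h (exact 95% interval 58.0 to 65.1) lay in the last 10% of the gene. Weaker enrichment in the tfiis-1 libraries, which would flatten peaks at gene ends and lift the sites between, stays open, with no test of it given here. An effect of the mutation on elongation stays open beside it, so the pattern is not called biological.

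The position of tfiis-1-higher summits near gene ends at 10 min is the next pattern. Calling other genes is argued against as the whole cause: in the 1834 genes called at both 10 min and 30 min, the 10 min position was further downstream by a median of 0.172 of the gene (bootstrap 95% interval 0.152 to 0.186), and in 75.7% of them, while the list medians of 0.782 and 0.508 lie further apart, so part of the shift stays open to it. A difference in depth, ChIP yield or scaling at 10 min stays open, with no test of it given here. The share of tfiis-1-higher summits does not settle it, since it was 98.11% at 10 min and 97.39% at 0 min, when 4.42% of these summits lay in the last 10% of the gene against 32.6% at 10 min. An early effect of heat in tfiis-1 stays open beside it.

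The growth of both lists with time is the last pattern. A single scaling factor that grows with time would lift one list and lower the other. The Col-0-higher summits were 74.4 times as many at 3 h as at 0 min (exact 95% interval 54.7 to 103.9), while the tfiis-1-higher list grew as well. This argues against such a factor as the whole cause only if the lists were filtered alike. The Col-0-higher lists held 15.1% of the highest peak number at 10 min and 53.6% at 30 min, and this is unknown at 0 min and 3 h. Unequal filtering could thus add to the growth, and the interval does not cover it. Deeper or better enriched libraries at later times cannot be told apart from a growing difference between the genotypes: summits were 9.65 times as many at 3 h as at 0 min, and no library totals were used here that could decide it.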

How the results depend on the processing

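Summit positions and shares at 30 min and 3 h kept direction and call under each alternative run (shares of 83.99% to 90.04% at 30 min and 68.7% to 79.85% at 3 h). With genes in place of summits, the tfiis-1-higher lists counted 4550 at 30 min and 6499 at 3 h, since a gene can hold several summits, and the 10 min share reversed against 0 min (97.7%, adjusted exact p = 1). A score of at least 2 times the lowest left 47 summits in the Col-0-higher list at 10 min. With the genes of any list as background, 9 pairs of lists shared more genes than expected, and the ratio of observed to expected reversed for tfiis-1-higher 3 h with Col-0-higher 3 h (0.748), for the opposite lists of 30 min (0.933) and for tfiis-1-higher 10 min with 3 h (0.860); of the 96 tests of a gene group in a list, 13 were above and 6 below expectation. This background holds only called genes, which raises the expected numbers. It is built from the same lists, which pushes pairs of lists below expectation, so a reversed ratio does not show that lists avoid each other. Neither background matches gene groups on signal, since the lists give no signal per gene. With summits within 500 bp in place of a shared gene, 11 pairs passed, and the opposite lists reversed at 3 h (0.267) and 30 min (0.327); this counts part of the shared genes against the expected number of all, so the ratio can only fall and does not test how close summits lie. With the highest-scoring 50% of Col-0-higher summits, an alternative chosen after seeing the data, the length difference was 508 bp at 10 min (no longer passing) and -174.5 bp at 30 min (reversed), and 0 large chaperone, co-chaperone or photosynthesis genes were left at 30 min; the cause was not tested. Without genes of both directions, also chosen after seeing the data, the length differences at 10 min, 30 min and 3 h passed with the sign kept. This alternative removes unequal parts of the opposite lists, so it does not test how stable the difference is. Over single gene groups and alternatives, 45 combinations kept direction and call, 24 lost the call with the direction kept, and 3 reversed. Those 3 were the groups left with 0 genes at 30 min.

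Leaving out organellar summits, or genes whose body does not hold the summit, moved nothing, as there were none. Stricter scores for shares, annotation classes, intron number and score-based choices in the 6 lists without scores were not run. No paired analysis was possible because the lists hold no value per replicate. Depth is unknown, so the lists do not show whether a site missing from one was tested with enough reads.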

Other observations

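Among the tests in this part, those of heat-response genes, and the reassignment of positions in genes called in both directions, were chosen after the results had been seen.

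At 10 min heat-response genes did not follow the other genes. Over the 89 genes of 4 groups (small heat shock proteins, large chaperones, heat shock transcription factors, co-chaperones), 32 were tfiis-1-higher at 10 min, with 36 summits at a median position of 0.25, where the other genes of that list had a median of 0.79. The difference was -0.54 of the gene (adjusted p = 4.00e-05 over 4 tests, two-sided permutation test). The 10 heat-response genes in the Col-0-higher list at 10 min had a median of 0.78 over 11 summits, against 0.37 in other genes, a difference of 0.41 (adjusted p = 0.00344, permutation test). At 3 h the heat-response genes were not shown to differ from the others by the same permutation test, with differences of -0.0096 in the tfiis-1-higher list (adjusted p = 0.848) and -0.020 in the Col-0-higher list (adjusted p = 0.261). HSP90.1 (AT5G52640), HSP70T-2 (AT2G32120), MTHSC70-2 (AT5G09590) and Hop3 (AT4G12400) are examples at 10 min. A hypothesis is that heat-response genes may have opposed positions in tfiis-1 and Col-0 at 10 min already; it was found and tested on the same lists, which do not show its cause.

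Genes called in both directions at one time allow the positions to be compared within a gene. At 3 h the median tfiis-1-higher summit lay upstream of the median Col-0-higher summit in 1545 of 1578 such genes (97.9%, exact 95% interval 97.1 to 98.6), at median positions of 0.35 and 0.97 and a median distance of 1698 bp. At 30 min it was so in 396 of 404 genes (98.0%, 96.1 to 99.1), with a median distance of 1847 bp. THO2 (AT1G24706), a subunit of the THO complex of mRNA export, had 1 tfiis-1-higher summit at position 0.17 and 7 Col-0-higher summits from 0.53 to 0.94 at 3 h. When the tfiis-1-higher positions were reassigned among these genes 1000 times, the median was 97.7% at 3 h (range 97.0 to 98.3) and 97.8% at 30 min (96.8 to 98.3). The order within genes thus restates the difference in position between the lists, and the hypothesis that S2P RNAPII is displaced upstream within genes in tfiis-1 was not decided by it.

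Sites near gene ends may change direction between 10 min and 3 h. In the 1242 genes that were tfiis-1-higher at 10 min and Col-0-higher at 3 h, summits lay within 500 bp of each other in 951 genes. When the relative positions of the 10 min summits were reassigned among these genes 1000 times, the number ran from 673 to 749. The reassignment moved relative positions between genes of different length, while closeness is counted in bp. A link between position and gene length could thus add to the excess. The count also takes summits at all positions, so it does not test gene ends alone. The last 10% of the gene held 31.0% of the 10 min summits in these genes and 33.7% in the other genes of that list. NRPB1 (AT4G35800) had its summits of both times 57 bp from the gene end. Libraries of different times are separate, so a scaling of the 10 min libraries (98.1% of summits tfiis-1-higher) together with the order at 3 h could give the same change.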
